A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

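Polyadenylated RNA from budding yeast, strain W303, was sequenced in 18 libraries, 3 in each of 6 groups. The cells came from asynchronous log-phase cultures in YPD and were ground frozen. RNA was taken either from affinity purifications or straight from the extract, extracted with Trizol, cleaned on Direct-zol columns, selected with the NEBNext poly(A) module and indexed with Illumina TruSeq unique dual indexes. 3 groups are purified nuclear pore complexes (NPCs): basket-containing pores on IgG, and basket-less pores and all NPCs on a GFP nanobody. A pair of groups are background purifications on the same matrices, the PrA control on IgG and the GFP control on the GFP nanobody. The last group is the total extract (input). The tagged proteins used to catch the pores are not given in the sources used here.

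By the submitters' processing notes, the authors aligned reads with STAR to the R64 build, counted them with featureCounts and used DESeq2. The deposited counts were used here as they stand, 1 column of raw counts per library over 7127 features. The aligner settings, strandedness and treatment of reads that map to several places are not given in the sources used here. Values for genes that overlap another gene on the opposite strand, for dubious open reading frames and for near-identical copies such as RPL41A with RPL41B or RPS28A with RPS28B are therefore uncertain.

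Of the 7127 features, 6047 matched the reference annotation by locus name, and 1080 did not: 674 open reading frames, 275 tRNAs, 82 small nuclear and nucleolar RNAs, 22 ribosomal RNAs, 18 other noncoding RNAs and 9 mitochondrial features. Lengths are coding lengths, without untranslated regions. Library totals ran from 10592840 to 16620246 counts. Between replicates of 1 group, the chi-square per degree of freedom of the counts, 1.00 under counting error alone, ran from 1.58 to 20.6. The highest values, 18.9 and 20.6, belong to replicate 3 of the PrA control against its partners.

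Each comparison was a contrast in 1 edgeR quasi-likelihood fit over the 18 libraries (filterByExpr, which kept 6429 genes, TMM factors, glmQLFit with robust=TRUE, glmQLFTest, two-sided). P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene is called at adjusted p below 0.05. Values are log2 fold changes ± standard error, the error being the absolute log2 fold change over the square root of F. The n is 3 libraries per group throughout. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say whether replicates are separate cultures. CPM values (counts scaled to library size) are means of 3 libraries scaled by TMM. All values are shares within a library, so amounts of RNA were not compared. A gene that fell over a control had a lower share there, and may still have come down in a larger amount.

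Basket-containing and basket-less pores were purified on different matrices, so their comparison is given both directly and as a difference of differences with each background control taken off. Named genes are, per comparison, the 10 with the largest positive and the 10 with the largest negative log2 fold change among called genes. They also had at least 20 CPM in the higher group and every library of 1 group above every library of the other. The last condition was not used for the difference of differences. Up to 4 members of each list described were added by smallest adjusted p, together with the basket genes MLP1, MLP2, NUP1, NUP2 and NUP60 and the markers URA3, HIS3, LEU2, TRP1 and ADE2.

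The 33 gene lists, the comparisons, the tests and the alternatives were written down before the data were examined. Of the lists, 31 had at least 5 measured members and were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted by Benjamini-Hochberg over lists. Members called are counted over all genes tested and adjusted over the list alone. Lists of noncoding RNAs, Ty elements, mitochondrial genes and alpha-cell markers are given as counts and medians, which was decided after some members were seen to change sign with the scaling. Spearman correlations of log2 fold change with coding length used the 5762 genes tested that have a length (89.6%). List medians were also set against 10000 random lists with the same spread over 20 length bins.

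The alternatives were DESeq2 size factors and upper-quartile factors in edgeR, no filter, a mean count of at least 50, nuclear open reading frames only, replicate number as a block, leaving out each library, fitting only the groups compared, glmTreat against a log2 fold change of 1, and the DESeq2 Wald test. Overlaps of comparisons that share controls were set against 20 simulations in which no group differed. Dividing the shared controls was not possible with 3 libraries.

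The pipeline was tested on simulated data with 200 of 6429 genes changed. In the data far more genes were called, from 32.9% between the controls to 90.3% for basket-containing pores over the PrA control. The rates below therefore need not hold for the data. For basket-containing over basket-less pores it called 96% of genes changed by 2 times and 100% of those changed by 4 times, and 4.84% of its calls were false. For the difference of differences it called 94% and 98%, and 5% of calls were false. Over the 12 comparisons false calls ran from 1.12% for basket-less pores over the GFP control to 7% for controls over input, and 5 exceeded 5%: that one, 6.63% for basket-containing pores over the PrA control, 6.25% for basket-less and 5.70% for basket-containing pores over input, and 6.19% between the controls.

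Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, matrixStats 1.5.0, Python 3.11.15 and matplotlib 3.10.9. Reads were not analysed here, so read positions, splicing and strand were not measured. Protein levels in the purifications are not given in the sources used here.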

Results

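RNA that came down with nuclear pore complexes (NPCs) of budding yeast was measured by poly(A) RNA sequencing in 18 libraries, 3 for each of 6 groups. mRNA leaves the nucleus through these pores, and the basket is the filamentous structure on their nuclear side. The groups were basket-containing pores (on IgG), basket-less pores and all NPCs (both on a GFP nanobody), a background control for each matrix (PrA control on IgG, GFP control on the nanobody) and the total extract (input). Library totals ran from 10592840 to 16620246 counts, and 6429 genes were tested. Ribosomal protein mRNAs made up 1.68 ± 0.05% of counts in basket-containing pores, 6.40 ± 0.07% in basket-less pores, 4.80 ± 0.07% in all NPCs, 12.2 ± 0.5% in the PrA control, 13.3 ± 0.2% in the GFP control and 14.8 ± 0.3% in input (mean ± SD, n = 3 each). Genes with a coding length of at least 3000 bases had the opposite order, 21.0 ± 0.48%, 14.4 ± 0.05%, 17.5 ± 0.15%, 8.80 ± 0.28%, 8.39 ± 0.07% and 8.32 ± 0.10%. The first principal component of log2 CPM held 71.7% of the variance and the second 15.6%. Across genes, which are not independent replicates, mean log2 CPM correlated at 0.994 between basket-less pores and all NPCs, 0.992 between the controls, 0.930 between basket-containing and basket-less pores and 0.805 between basket-containing pores and the PrA control.

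Which mRNAs held a larger share in basket-containing pores than in the IgG background? The mRNA of MLP1, which encodes the main filament protein of the basket, was at 5453 CPM against 287 in the PrA control, a log2 fold change of 4.25 ± 0.04 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.57e-30, n = 3 per group). Other basket mRNAs rose less: NUP1 by 2.17 ± 0.05, MLP2 by 1.91 ± 0.05 and NUP2 by 0.80 ± 0.04, while NUP60 fell by 0.32 ± 0.06. The largest rises were in GAC1 (5.61 ± 0.07, 3304 against 67.5 CPM), a protein phosphatase 1 subunit for glycogen, PHO89 (5.59 ± 0.06), a sodium-phosphate cotransporter, and MTL1 (5.13 ± 0.14), a cell wall stress sensor. YAK1 (4.77 ± 0.06), a kinase of glucose signalling, and MGA1 (4.64 ± 0.10), a heat shock factor relative, were also among the 10 largest. The other 5 were YGR022C, at the MTL1 locus, YDR149C, YBL065W, YPR160C-A and the noncoding RNA PWR1, none of them established coding genes.

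Among the 10 largest falls against the PrA control, GRE2, a methylglyoxal reductase, fell by 4.23 ± 0.08 (11.9 against 224 CPM), as did CYC1, cytochrome c (15.9 against 292 CPM), the pseudogene AAD6 (-4.18 ± 0.06) and ARG3, an arginine synthesis enzyme (-4.11 ± 0.15). AAD6 was also far higher in the controls than in input, as given under other observations. RPL41A fell by 4.08 ± 0.35, with reads it may share with RPL41B. YOL150C, which lies beside GRE2, fell by 4.91, and YIL014C-A, YDR524W-C, snR17b and snR76 completed the 10. In all, 2813 genes rose and 2991 fell, and 1609 of the rises and 1841 of the falls were more than 2-fold. With upper-quartile factors 2296 rose and 3546 fell (39.3% of calls higher, against 48.5%).

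By fixed list, of 81 large-subunit ribosomal protein mRNAs 0 rose and 80 fell in basket-containing pores against the PrA control (median -2.55, RPL10 -3.32 and RPL16B -2.96), and of 57 small-subunit ones 0 rose and 57 fell (median -2.49, ASC1 -3.35 and RPS4A -3.07). Their camera adjusted p values (Benjamini-Hochberg) were 3.58e-18 and 1.87e-15, but adjusted p = 0.113 and adjusted p = 0.0818 with an estimated correlation. Ribosome biogenesis mRNAs fell in 98 of 104 (median -1.45, GAR1 -2.52, NOP1 -2.72), camera adjusted p = 6.51e-14 by Benjamini-Hochberg and adjusted p = 0.0818 with an estimated correlation. General stress mRNAs rose in 26 of 30 and fell in 2 (median 2.14, with TPS2 4.13 and GLC3 4.25, of trehalose and glycogen synthesis), and this call held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0457). So did the fall of nuclear-encoded oxidative phosphorylation mRNAs, 6 up and 30 down of 36 (median -1.33, ATP7 -2.09, COX5A -1.69, against NDI1 2.28), at the same adjusted p = 0.0457 by Benjamini-Hochberg. Heat shock and chaperone mRNAs were not called as a list (17 higher and 11 lower of 29, median 0.56; camera, Benjamini-Hochberg adjusted p = 0.309). Nucleoporin mRNAs rose in 25 of 33 and fell in 7 (median 0.79, NUP116 2.13), camera adjusted p = 0.00239 by Benjamini-Hochberg but adjusted p = 0.202 with an estimated correlation. Every count in these lists was the same adjusted over the list alone.

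Which mRNAs held a larger share in basket-less pores than in the GFP nanobody background? Basket mRNAs rose here too: MLP2 by 1.51 ± 0.05, NUP1 by 1.21 ± 0.04, MLP1 by 1.02 ± 0.04 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.00e-18, n = 3 per group) and NUP2 by 0.71 ± 0.04, while NUP60 fell by 0.30 ± 0.06. The mitochondrial COX1 transcript (4.78 ± 0.21, 53.4 against 1.94 CPM) and its intron reading frames AI2 (4.60 ± 0.21) and AI5_BETA stood at the top. AI5_BETA had 0.213 CPM in the control, too few counts for a fold change. In these poly(A)-selected libraries mitochondrial features made up only 0.047% of counts in basket-less pores and 0.024% in the GFP control. PHO89 (4.49 ± 0.06), GAC1 (4.18 ± 0.07), MGA1 and MTL1 (3.89 ± 0.14) followed, genes that also led over the PrA control, with YGR022C, YPR160C-A and JIP3 (3.56 ± 0.25), a dubious frame overlapping YLR332W, also among the 10.

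The falls against the GFP control were largest in RDN5-1 (-5.91 ± 0.86), a 5S ribosomal RNA gene with uneven counts between libraries, AAD6 (-5.05 ± 0.07), the oxidoreductase mRNA OYE3 (-4.23 ± 0.06, 11.6 against 216 CPM) and the glutathione transferase mRNA GTT2 (-3.87 ± 0.07). YLR140W (-4.57 ± 0.53, but -5.58 without replicate 3 of the basket-less pores), ARG3, RPL41B, snR76, MHF1 (-3.26 ± 0.10), a DNA repair factor, and YOL150C completed the 10. AAD6 and GTT2 were far higher in the background controls than in input, as given under other observations. Their falls over a control, here and in all NPCs, therefore need not mean that pores held less of them than the extract. In all, 3025 genes rose and 2282 fell (57.0% of calls higher); with upper-quartile factors 2203 rose and 3125 fell (41.3%), so which side is larger depends on the scaling.

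Ribosomal protein mRNAs fell again in basket-less pores, 77 of 81 large-subunit (median -1.11, RPL42A -1.77) and 55 of 57 small-subunit (median -1.04, RPS14A -1.93), with 3 and 1 rising. Camera adjusted p values (Benjamini-Hochberg) were 9.96e-21 and 1.14e-17, against adjusted p = 0.103 and adjusted p = 0.0762 with an estimated correlation. Ribosome biogenesis mRNAs did not follow them: 48 rose and 40 fell (NOP58 1.14, the ribosome-maturation ATPase REA1 1.09, NOP10 -1.60; camera, Benjamini-Hochberg adjusted p = 0.838). Their median was 0.02, but -0.10 with DESeq2 size factors and -0.25 with upper-quartile factors, and the test pointed down while the mean was 0.06. Oxidative phosphorylation mRNAs fell in 30 of 36 and rose in 2 (median -0.74, COX5A -1.59, CYC1 -2.93), the only call that held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.00317). General stress mRNAs rose in 23 of 30 and fell in 7 (median 1.29, GLC3 3.41, TPS2 2.69), camera adjusted p = 9.78e-04 by Benjamini-Hochberg and adjusted p = 0.0762 with an estimated correlation. Nucleoporin mRNAs rose in 26 of 33 and fell in 3 (median 0.49, NUP170 1.40), camera adjusted p = 0.00154 by Benjamini-Hochberg and adjusted p = 0.221 with an estimated correlation. The counts were the same adjusted over the list alone.

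Which mRNAs held a larger share in all NPCs than in the same background? MLP2 rose by 1.75 ± 0.05, MLP1 by 1.67 ± 0.04 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.95e-23, n = 3 per group), NUP1 by 1.38 and NUP2 by 0.77, and NUP60 fell by 0.41. COX1 (6.03 ± 0.19), AI2 (5.09 ± 0.20), GAC1 (4.76), PHO89 (4.67), YGR022C, MTL1 (4.26), MGA1 (4.17), YDR149C and JIP3 rose most, with AI5_BETA at 224 CPM against 0.213 CPM. RDN5-1, YLR140W, AAD6 (-4.87), OYE3 (-4.11), YOL150C, GTT2 (-3.96), RPL41B, RPS28B, ARG3 (-3.58) and RPS28A fell most. In all, 3015 genes rose and 2416 fell (55.5% of calls higher), against 2315 and 3183 (42.1%) with upper-quartile factors.

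In all NPCs 78 of 81 large-subunit ribosomal protein mRNAs fell (median -1.61) and 56 of 57 small-subunit ones (median -1.53), camera adjusted p = 4.21e-23 and 3.77e-19 by Benjamini-Hochberg. With an estimated correlation these were adjusted p = 0.103 and adjusted p = 0.0786. Oxidative phosphorylation mRNAs fell in 33 of 36 (median -0.95, COX5A -1.91, ATP7 -1.79), again the only call to hold with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.00278). General stress mRNAs rose in 22 of 30 and fell in 7 (median 1.38, TPS2 3.04), camera adjusted p = 0.00233 by Benjamini-Hochberg and adjusted p = 0.108 with an estimated correlation. Nucleoporin mRNAs rose in 25 of 33 and fell in 5 (median 0.71, NUP170 1.88), camera adjusted p = 0.0014 by Benjamini-Hochberg and adjusted p = 0.209 with an estimated correlation. Counts adjusted over the list alone were the same.

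fry tests whether the genes of a set move on balance one way and, in its mixed form, whether they change in either direction. Neither compares the set with other genes. For ribosome biogenesis in basket-less pores over the GFP control the fry adjusted p (Benjamini-Hochberg) was 0.00406 and the mixed one 1.92e-17, while camera made no call.

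How do basket-containing and basket-less pores differ? MLP1 mRNA was the most different of the genes higher in basket-containing pores, 5453 against 521 CPM, a log2 fold change of 3.39 ± 0.04 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.52e-28, n = 3 per group). With each background control taken off it was 3.23 ± 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.86e-24). MLP1 (YKR095W) lies on chromosome XI at 619805 to 625432 in R64. The basket mRNA NUP1 (YOR098C, XV 507948 to 511178) was higher by 1.04 ± 0.04 and MLP2 (YIL149C, IX 63028 to 68067) by 0.30 ± 0.05. NUP60 did not pass (-0.04 ± 0.06), and NUP2 was at -0.08 ± 0.04 with a sign and a call that depend on the scaling and on single libraries. Among those after MLP1 were YGR022C (2.27), at the MTL1 locus, and MTL1 itself (YGR023W, VII 529264 to 530919) at 2.00 ± 0.12. SWC7, a subunit of the SWR1 chromatin remodeller, was at 2.01 ± 0.16. The others were YBL065W, YLR338W, YPL136W, YDL034W, YJL175W and YHR165W-A, reading frames given here only by locus name. Strandedness is not given, so such frames, YGR022C included, may carry reads of an overlapping gene and need not be separate hits.

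Lower in basket-containing pores were RPC31, a subunit of RNA polymerase III (YNL151C, XIV 347766 to 348521), by 3.70 ± 0.07 (142 CPM in basket-less pores, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.23e-24) and the ribosome assembly factors LOC1 (-3.10 ± 0.09) and NOP7 (-3.07 ± 0.09). RPP0 (YLR340W, XII 805887 to 806825), a ribosomal stalk protein, was lower by 3.05 ± 0.05, and YLR339C (-3.06) is a dubious frame over it. The mitochondrial COX1 (-4.34 ± 0.21), AI5_BETA (-3.85 ± 0.13), AI2 (-3.60), SCEI (-3.18 ± 0.21), an intron endonuclease, and 21S_RRNA were the others of the 10. In all, 2591 genes were higher and 2712 lower, more than 2-fold in 713 and 1203. With the controls taken off, 2355 were higher and 2540 lower. Which side is larger depends on the settings: DESeq2 size factors gave 2908 and 2418, or 2707 and 2209 with the controls taken off, and leaving out replicate 3 of the basket-containing pores gave 2840 and 2342.

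**Figure D1:**
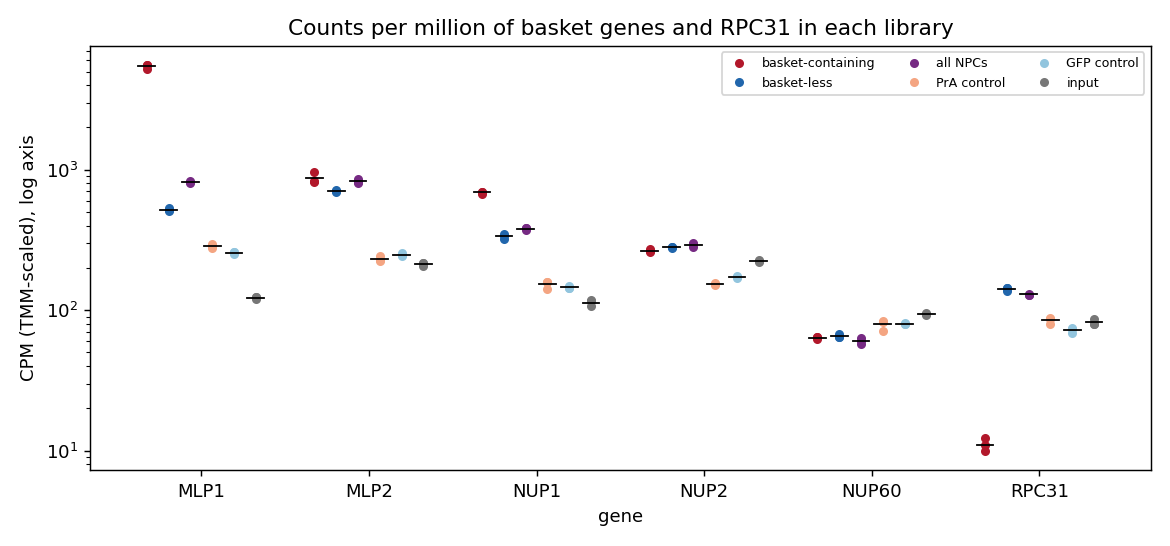
CPM of the 5 basket genes and RPC31 in each of the 18 libraries, log scale, with bars at the group means (n = 3). MLP1 was highest and RPC31 lowest in basket-containing pores.

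Of 104 ribosome biogenesis mRNAs, 98 were lower in basket-containing than in basket-less pores and 2 higher (median -1.47, GAR1 -2.42, NOP1 -2.58, EBP2 -2.55, CBF5 -2.44). Camera gave adjusted p = 3.21e-18 (Benjamini-Hochberg), but adjusted p = 0.111 with an estimated correlation. The medians of random lists of the same coding lengths had themselves a median of 0.17, and none of the 10000 lay as low. Subunits of RNA polymerases I and III were lower in 16 of 20 and higher in 2 (median -1.36, RPA34 -2.98, RPC40 -2.23), camera adjusted p = 3.35e-04 by Benjamini-Hochberg and adjusted p = 0.148 with an estimated correlation. Translation factors were lower in 25 of 29 (median -1.54, TEF1 -2.12, TEF4 -1.74), camera adjusted p = 7.60e-07 by Benjamini-Hochberg and adjusted p = 0.16 with an estimated correlation. Ribosomal proteins were lower in 78 of 81 large-subunit (median -1.53, RPL5 -2.10) and 57 of 57 small-subunit mRNAs (median -1.52, ASC1 -2.58), camera adjusted p = 3.98e-17 and 4.44e-15 by Benjamini-Hochberg. With an estimated correlation these were adjusted p = 0.16 and adjusted p = 0.148. General stress mRNAs were higher in 27 of 30 and lower in 1 (median 1.15, TPS2 1.64, MSC1 1.59, GPH1 1.48), which held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0428). Nucleoporin mRNAs were higher in 19 of 33 and lower in 8 (median 0.22, NUP116 1.46, SEH1 -1.27), not called by camera (Benjamini-Hochberg adjusted p = 0.0639). With the controls taken off, the medians were -1.43 for biogenesis, -1.21 for the polymerases, -1.57 for translation factors and 1.02 for stress. Against input the stress median was 1.58 in basket-containing pores, 0.48 in basket-less pores and 0.62 in all NPCs. In that order, polymerase medians were -2.42, -0.49 and -0.66, and translation factor medians -2.06, -0.46 and -0.66. All NPCs thus lay nearer basket-less pores, on the same nanobody, so matrix and basket effects cannot be told apart. Counts adjusted over the list alone were the same.

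**Figure D2:**
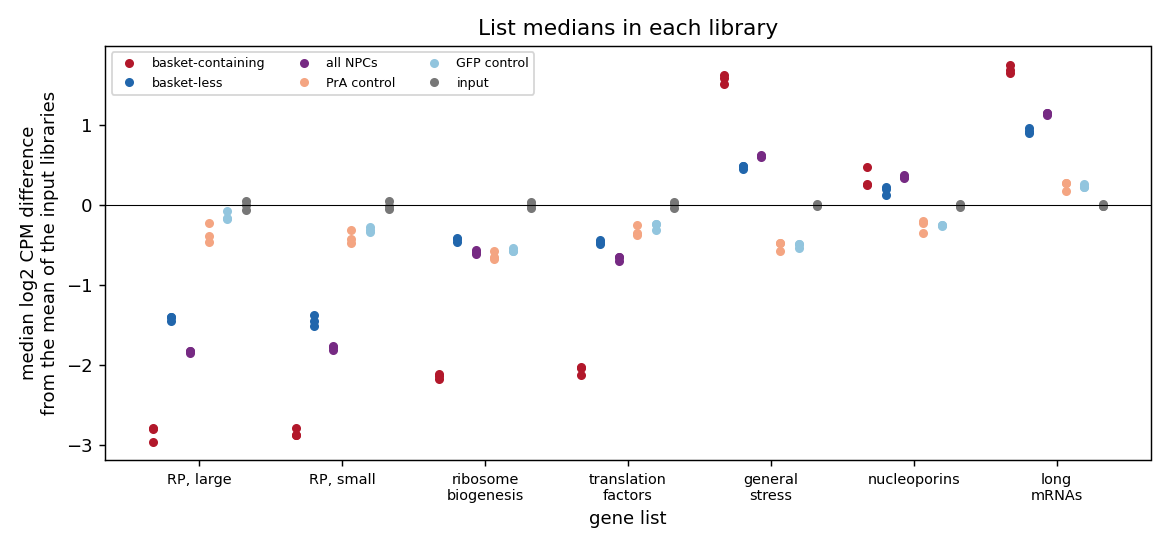
Median log2 CPM of 7 gene lists in each library, as the difference from the mean of the input libraries. Ribosome biogenesis mRNAs were lowest in basket-containing pores, while the sign of their median in basket-less pores over the GFP control turns with the scaling.

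How do basket-less pores differ from all NPCs on the same matrix? The differences were small: 1305 genes were higher and 1468 lower in basket-less pores, but only 4 and 24 by more than 2-fold, and with upper-quartile factors 1483 were higher and 1324 lower. MLP1 was lower by 0.65 ± 0.04 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.51e-12, n = 3 per group), MLP2 by 0.23 ± 0.05 and NUP1 by 0.18, while NUP2 (-0.06) and NUP60 (0.11) did not pass. Higher in basket-less pores were ASC1 (0.69 ± 0.04, 889 against 551 CPM), RPL25 (0.66), RPL1B (0.61), RPL10 (0.60), RPL21A (0.57), CDC36 (0.61 ± 0.09), of the Ccr4-Not complex, and RPE1 (0.58), of the pentose phosphate pathway. The mitochondrial SCEI (0.94 ± 0.17) and 21S_RRNA and YLR076C, a dubious frame over RPL10, were the others. Lower were COX1 (-1.26 ± 0.12), SEC10 (-0.73 ± 0.06), an exocyst subunit, SLK19 (-0.72 ± 0.08), a spindle protein, and NIP100 (-0.69), a dynactin subunit. YDR261C-D, YJL197C-A, YLR342W-A, YDR149C, YJL113W and ENV11 completed the 10.

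Ribosomal protein mRNAs were higher in basket-less pores than in all NPCs in 71 of 81 large-subunit (median 0.42) and 56 of 57 small-subunit mRNAs (median 0.41), or 74 and 57 adjusted over the list alone. Both calls held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.047 and 0.0426). Genes of the cytoskeleton, motors and other long mRNAs were lower in 32 of 40 and higher in 4 (5 adjusted over the list alone; median -0.27, IRA2 -0.55, IRA1 -0.53, ACT1 0.44), which also held (Benjamini-Hochberg adjusted p = 0.0426). Oxidative phosphorylation (21 higher and 1 lower of 36, median 0.18), mitochondrial ribosomal protein (30 and 1 of 73, median 0.14) and secretory pathway mRNAs (29 and 9 of 64, median 0.10) held as well, at Benjamini-Hochberg adjusted p = 0.0426, 0.0459 and 0.0426. Adjusted over the list alone their counts were 23 and 2, 32 and 1, and 30 and 9. Nucleoporin mRNAs were lower in 20 of 33 and higher in 4 (median -0.18, MLP1 -0.65, NUP188 -0.60, NUP133 -0.62), camera adjusted p = 3.31e-04 by Benjamini-Hochberg and adjusted p = 0.131 with an estimated correlation. Ribosome biogenesis mRNAs were higher in 45 of 104 and lower in 4 (5 adjusted over the list alone; median 0.13, GAR1 0.41), camera adjusted p = 1.20e-05 by Benjamini-Hochberg and adjusted p = 0.22 with an estimated correlation.

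How does coding length relate to what came down? Of 491 genes of at least 3000 bases, 424 rose and 48 fell in basket-containing pores over the PrA control (median 1.35), 417 and 31 in basket-less pores over the GFP control (0.81) and 444 and 23 in all NPCs (1.11). The list of cytoskeleton, motor and other long mRNAs rose in 34, 38 and 36 of 40 (medians 1.43, 0.72 and 0.96; IRA2, a Ras GTPase activator, by 4.11, 3.06 and 3.61). Camera called it each time, at Benjamini-Hochberg adjusted p = 3.53e-06, 1.96e-07 and 3.02e-07, against adjusted p = 0.0818, 0.0762 and 0.0786 with an estimated correlation. Its medians and those of the nucleoporin list lay within the range of random lists of equal coding length, whereas general stress mRNAs lay above all 10000 of them. Spearman rho of log2 fold change with coding length was 0.57, 0.53 and 0.58 over matched controls, 0.45 for basket-containing over basket-less pores and -0.56 for basket-less pores over all NPCs, across 5762 genes that are not independent replicates. Between the PrA and GFP controls it was 0.18, and between the controls and input -0.12. With GC content of the coding sequence, rho was 0.50 for controls over input and 0.48 for basket-less pores over all NPCs. Over matched controls it was -0.13, -0.32 and -0.39 for basket-containing pores, basket-less pores and all NPCs.

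**Figure D3:**
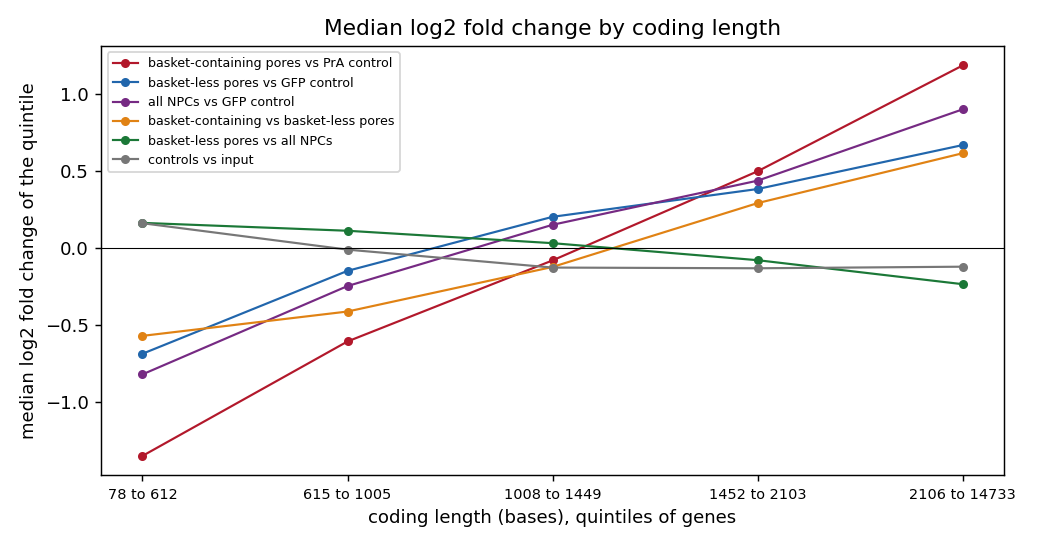
Median log2 fold change by coding-length quintile in 6 comparisons. From the shortest to the longest quintile the median went from -1.35 to 1.19 for basket-containing pores over the PrA control and from 0.16 to -0.23 for basket-less pores over all NPCs.

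How far do the pore comparisons share genes? Basket-less pores and all NPCs, both over the GFP control, shared 2815 higher genes (1419 by independence) and 2157 lower genes (858 by independence). Their log2 fold changes correlated at 0.970 across genes (0.495 simulated) with covariance 1.07 (0.0101 simulated, difference 1.06). Part of the excess may come from the shared control libraries, which are too few to be divided. Basket-containing pores over the PrA control and basket-less pores over the GFP control share no controls; 2352 genes were higher in both (1324 by independence) and 1961 lower in both (1062), while 147 and 486 went opposite ways.

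How do the pore purifications compare with the total extract? Over input, basket-containing pores had 2822 genes higher and 2927 lower (2309 and 3487 with upper-quartile factors), led by MLP1 (5.48), YGR022C, MTL1 (4.97) and HKR1 (4.51 ± 0.09), a mucin-type osmosensor, and at the other end by RPS12 (-4.65) and RPL38 (-4.60). Basket-less pores had 2830 higher and 2319 lower (55.0% higher, but 39.2% with upper-quartile factors), with AI5_BETA (too few input counts for a fold change), COX1 (5.71), AI2 (5.13) and PHO89 (3.18) against RPL38 (-3.06) and ARG3 (-3.05). All NPCs had 2868 higher and 2384 lower (54.6%, but 40.2% with upper-quartile factors), with AI5_BETA, COX1 (6.97) and AI2 (5.63) against RPL38 (-3.53). Ribosome biogenesis mRNAs were lower in 101 of 104 in basket-containing pores (median -2.16), camera adjusted p = 3.86e-17 by Benjamini-Hochberg and adjusted p = 0.0785 with an estimated correlation. Comparisons over input share the input libraries: the covariances were 1.16, 1.35 and 0.802, above the simulated ones by 1.15, 1.34 and 0.791, part of which may come from the shared libraries. Basket-containing pores over all NPCs, on different matrices, had 2489 genes higher and 2678 lower (2868 and 2324 with DESeq2 size factors), with MLP1 (2.74), YGR022C, YLR338W, YPL136W, YBL065W and the cell wall mRNA HSP150 (1.69 ± 0.04) against COX1 (-5.60), AI5_BETA, AI2, YDR261C-D and RPC31 (-3.56).

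Which camera calls hold with an estimated correlation? The totals are out of the 31 lists tested, those of noncoding RNAs and Ty elements included. In the order basket-containing, basket-less and all NPCs, 14, 18 and 20 lists were called over input and 0, 1 and 4 held. Over matched controls 13, 12 and 14 were called and 2, 1 and 1 held, and for basket-containing over basket-less pores 12 and 1 (11 and 1 with controls taken off, and 11 and 1 over all NPCs). Of basket-less pores against all NPCs 19 were called and 8 held, among them intron-containing ribosomal protein genes (86 of 90 higher, median 0.40, Benjamini-Hochberg adjusted p = 0.0426) and biosynthetic genes (21 of 29 higher, median 0.17, Benjamini-Hochberg adjusted p = 0.0445). Between the controls 7 were called and over input 12, and none held.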

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

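Apart from the pair of tests on the coding length of list members, the tests weighed here were chosen only after the results were seen.

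A tested difference between groups is given first, with the value of each gene the rules name. Basket-containing against basket-less pores, each over its own control, differed in 2355 genes higher and 2540 lower, and basket-less pores differed from all NPCs in 1305 higher and 1468 lower. The larger side turned in both, to 2707 and 2209 with DESeq2 size factors and to 1483 and 1324 with upper-quartile factors. Among basket genes with the controls taken off, MLP1 mRNA was higher by 3.23, NUP1 by 0.97 and MLP2 by 0.40. At the high end too were MCO14 (2.30), a mitochondrial protein, the DNA-repair gene SAE2 (2.14), YGL217C (2.03), YDR431W (2.02), YDL034W (2.01), YBL065W (2.00), YHR056W-A (2.00) and YPL136W (1.99). Reading frames given only by locus name may carry reads of an overlapping gene, since strandedness is not given. YLR140W (2.65 ± 0.86) had few and uneven counts, and its value was 3.66 without replicate 3 of the basket-less pores. At the low end stood polymerase and ribosome-assembly mRNAs, RPC31 (-3.92), RPA34 (-3.36), LOC1 (-3.02) and NOP1 (-2.96), with YLR339C (-3.08) over RPP0, the mitochondrial COX1 (-3.47) and the Ty frame YDR261C-D (-3.03). SPE3 (-3.58), a spermidine synthase, RPD3 (-3.32), a histone deacetylase, and PFA4 (-3.04), a palmitoyltransferase, were low too, and the PrA control held more of each than the GFP control: 484 against 216, 833 against 153 and 211 against 33.0 CPM. Of the marker genes, LEU2 was higher by 1.05 and HIS3 by 1.04, while URA3 (-1.34) and ADE2 (-0.46) were lower.

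The rise of log2 fold change with coding length was seen in all 3 kinds of pore purification. Short ribosomal protein mRNAs alone do not make it, since without those genes and given level the lowest of the 3 rho values was 0.469. Nor do controls that prefer short mRNAs make it alone, since over input the lowest rho was 0.439. Better kept RNA in the pore samples might favour long mRNAs, and the share of counts from genes of at least 3000 bases, 21.0% in basket-containing pores, cannot tell, because read positions are not in the counts. Whether long mRNAs are more often at the pore in the cell stays open and was not tested, and the counts hold no measure of passage or time at the pore.

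Ribosome biogenesis mRNAs were lower in basket-containing than in basket-less pores, and so were ribosomal protein mRNAs. Background binding, as the controls show it, argues little for the first, as the biogenesis median with each control taken off was -1.43. That step cannot remove an effect of the matrix on the pore purification itself. The biogenesis median against input was -2.14 in basket-containing pores on IgG, but -0.43 in basket-less pores and -0.59 in all NPCs, both on the nanobody. A matrix effect thus cannot be told from a basket effect. Other mRNA levels in the cells used for the basket-containing purification could also lower both lists. That was not tested, because the strain of the input is not stated beyond W303. Coding length does not account for either list (percentile 0 among length-matched lists for biogenesis and 0 for ribosomal proteins). If more RNA like the GFP control were carried into the basket-less purification, its values would lie between the others. In plain CPM, however, 45.2% of biogenesis members (47 of 104, against 15.8% of all genes) were higher in basket-less pores than in both basket-containing pores and the GFP control. Another 41 lay between. With TMM, DESeq2 and upper-quartile factors, chosen after seeing the data, 47, 44 and 34 lay above both. Carry-over of RNA like the GFP control may thus add to the difference but does not make it alone. Carry-over of RNA like the extract was not tested, and the basket-less median against input, -0.43, lies between basket-containing pores and input. For ribosomal proteins only 2.90% (4 of 138) lay above both, so carry-over may explain part of their difference and cannot be told from a real one. Whether pores without a basket meet more of these mRNAs in the cell is an untested hypothesis; imaging such an mRNA at both kinds of pore would be 1 test of it.

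MLP1 mRNA was higher in basket-containing than in basket-less pores. The general rise of long mRNAs there does not account for it, since its log2 fold change exceeded that of the next of the 491 genes of at least 3000 bases, HKR1 (1.73 ± 0.08), by 1.66. A higher MLP1 mRNA level in the cells used for that purification could raise it, and its log2 fold change of 5.48 over input cannot tell, because the strain of the input is not stated beyond W303. On IgG, basket-containing pores held MLP1 mRNA at 5258 to 5551 CPM. On the nanobody, basket-less pores held it at 512 to 532 CPM and all NPCs at 806 to 831. A matrix effect therefore cannot be told from a basket effect here either. On the nanobody alone, MLP1 was still lower in basket-less pores than in all NPCs. Capture of tagged protein with the mRNA it is being made from is another possible source, untested. The tagged proteins are not given in the sources used here. Whether MLP1 mRNA is itself held at the basket is a hypothesis these counts cannot test; a purification after ribosomes are released from mRNA would be 1 test of it.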

How the results depend on the processing

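How far do other choices change the results? DESeq2 size factors, upper-quartile factors, no filter, a mean count of at least 50, nuclear open reading frames only, the replicate block and the DESeq2 Wald test left all 24 counts of called genes within 1.5 times, though the larger side could turn. For basket-containing over basket-less pores it turned with DESeq2 size factors (2908 higher and 2418 lower), no filter (2891 and 2431) and the DESeq2 Wald test (2881 and 2387), against 2591 and 2712. Other settings shifted the log2 fold changes of genes as a whole, given as the median over genes of the difference from the reported value, taken over the genes tested both ways. DESeq2 size factors shifted them by -0.11 for basket-less pores and all NPCs over input, -0.12 for both over the GFP control, 0.13 for basket-containing over basket-less pores and over all NPCs and 0.14 with controls taken off, and the DESeq2 Wald test by the same amounts. Upper-quartile factors shifted them by -0.33, -0.25 and -0.27 over input and -0.34, -0.27 and -0.29 over matched controls for basket-containing, basket-less and all NPCs. Without a filter the shift was -0.11 for basket-less pores over the GFP control and 0.12 for basket-containing over basket-less pores, over all NPCs and with controls taken off, and with only the groups compared it was -0.13 for both GFP-control comparisons. Replicate numbers did not pair the libraries as a whole (45 same-number pairs, median correlation -0.002, range -0.161 to 0.280). The own number was the best match in 16 of 45, among them each pair of basket-containing with basket-less pores (0.05 to 0.07). A batch shared by some groups was not excluded. With number as a block basket-containing over basket-less pores had 2596 genes higher and 2718 lower, 5290 of the 5303 calls being kept. Dividing the shared controls was not possible.

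glmTreat against a log2 fold change of 1 gives fewer genes by construction. Over input it called 1501 higher and 1566 lower for basket-containing pores, 573 and 394 for basket-less pores and 803 and 537 for all NPCs. Over matched controls it called 1477 and 1613, 701 and 524, and 1004 and 728 in the same order. For basket-containing over basket-less pores it called 516 and 932, with controls taken off 370 and 825, and over all NPCs 230 and 717. Basket-less pores over all NPCs had 0 higher and 1 lower by glmTreat, where 3207 genes had an unadjusted p under 0.05 in the edgeR quasi-likelihood test and the DESeq2 Wald test called 1294 higher and 1400 lower. The PrA control over the GFP control had 21 and 1, and controls over input 350 and 344.

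The comparison of the PrA and GFP controls was the least steady. With only the groups compared it had 545 genes higher and 437 lower against 1038 and 1075. Leaving out 1 library gave 603 to 1431 higher and 621 to 1480 lower, with 603 and 628 without replicate 1 of the PrA control, 638 and 621 without its replicate 2, and 678 and 712 without replicate 2 of the GFP control. Replicate 3 of the PrA control lies apart, and the cause was not tested. Basket-containing over basket-less pores had 2508 to 2840 higher and 2342 to 2672 lower, and the larger side turned without replicate 3 of the basket-containing pores (2840 and 2342).

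Among the named genes small values changed sign, with adjusted p (edgeR quasi-likelihood or DESeq2 Wald, Benjamini-Hochberg) from 0.0034 to 0.992. For basket-containing over basket-less pores NUP2 was 0.0472 with DESeq2 size factors, 0.0399 without a filter, 0.047 in the DESeq2 Wald test and -0.0915 to 0.024 when 1 library was left out, against -0.08; its call was lost without any 1 library of either kind of pore. NUP60 was 0.0945, 0.0877, 0.0945 and -0.0485 to 0.089 in the same order, against -0.04. With the controls taken off it was 0.1164, 0.093, 0.1155 and -0.094 to 0.0932, against -0.02. Both upper ends came without replicate 3 of the basket-containing pores. Without that library NUP2 with controls taken off also passed, at 0.1888 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00306). Between the controls NUP60 was 0.0013 with only the groups compared and -0.0543 to 0.0571 when 1 library was left out, the upper end without replicate 3 of the PrA control. With upper-quartile factors NUP2 in basket-containing pores over input was -0.082, and LEU2 over the GFP control was -0.1055 in basket-less pores and -0.1347 in all NPCs. For basket-less pores over all NPCs LEU2 was -0.0069 to 0.0268 when 1 library was left out, negative without replicate 1 of either group, and TRP1 was -0.0982 to 0.0201, positive only without replicate 2 of the basket-less pores. No other named gene changed direction, and the cause was not tested. Members of the lists given only as counts and medians, set aside after sign changes were seen, were left out of this check unless another rule named them.

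Camera with an estimated correlation kept fewer lists. Over input it called 0 higher and 0 lower for basket-containing pores, 0 and 1 for basket-less pores and 1 and 3 for all NPCs. Over matched controls it called 1 and 1, 0 and 1, and 0 and 1. Basket-containing over basket-less pores had 1 and 0, with controls taken off 1 and 0, and over all NPCs 1 and 0. Basket-less pores over all NPCs had 7 and 1, the PrA over the GFP control 0 and 0, and controls over input 0 and 0. By camera with the preset correlation those last 2 comparisons had 1 and 6 and 4 and 8.

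Among genes above the median level only, the rho with coding length was 0.569, 0.497 and 0.602 over input and 0.621, 0.576 and 0.653 over matched controls for basket-containing, basket-less and all NPCs. It was 0.532 for basket-containing over basket-less pores, 0.503 with controls taken off, 0.416 for basket-containing pores over all NPCs, -0.766 for basket-less pores over all NPCs and -0.100 for controls over input.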

Other observations

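The background purifications were not a copy of the extract. The strain of the input is not stated beyond W303, so a difference between the cells used cannot be told from background binding. Such a difference could also enter the values of pores over controls, and was not tested. Controls over input had 2494 genes higher and 2773 lower (2542 and 2531 with only the groups compared), with the pseudogene AAD6 (4.54 ± 0.06; 696 and 812 CPM in the controls against 32.4) and the glutathione transferase GTT2 (3.73 ± 0.06) highest among well-counted genes, while RDN5-1 (4.18 ± 0.84) ran from 3.47 without replicate 3 of the PrA control to 4.84 without replicate 3 of the input. URA3 stood at 3.02 ± 0.04, with 1828 and 1720 CPM in the controls against 218 in input. The serine deaminase CHA1 (-3.16 ± 0.06) was at the low end, after YGR265W (-3.28), followed by DDR48 (-2.94), a stress protein, and MTD1 (-2.50), of folate metabolism. Mitochondrial ribosomal protein mRNAs were higher in 55 of 73 and lower in 8 (median 0.42), camera adjusted p = 9.63e-07 by Benjamini-Hochberg and adjusted p = 0.112 with an estimated correlation. In a separate fit of only these 9 libraries as a pair of groups, which called 5082 genes in place of 5267, the real split was 1 of 84 with as many. The highest other, the GFP controls alone against the rest, gave 1709. The controls also differed from each other, in 2113 genes, so the splits were not interchangeable. The rank therefore cannot exclude chance or a batch that follows the groups, and the labels do not say whether the libraries are independent.

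The IgG and nanobody backgrounds differed in 1038 genes higher and 1075 lower in the PrA control, counts that ran from 603 to 1431 and from 621 to 1480 when 1 library was left out and were 545 and 437 with only the groups compared. SNF1, the kinase of glucose repression, was higher by 2.69 ± 0.04 (861 against 133 CPM), PFA4 by 2.68 ± 0.06, RPD3 by 2.44 ± 0.07 and BSD2 by 2.40. OAF1 (1.76), SRO9 (1.73), KCS1 (1.72), NMA1 (1.70), EOS1 and MMF1 followed, a set with no shared pathway among the fixed lists. RDN5-1 was lowest (-2.90 ± 0.62, but -4.32 without replicate 3 of the PrA control), then YLR140W and QRI7 (-1.33 ± 0.26). Camera called 7 lists with the preset correlation and none with an estimated one (lowest adjusted p = 0.815 by Benjamini-Hochberg with an estimated correlation). Replicate 3 of the PrA control lay apart from its partners, and a split that set it with a pair of GFP controls gave 804 genes against 2113 for the real one, 1 of 10 with as many.

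Genes of adenine synthesis, 10 genes grouped after their values were seen and so not independent evidence of a direction, were lower in basket-containing than in basket-less pores in 9 and higher in 1 (median -1.06). ADE13 was at 228, 1122 and 927 CPM in basket-containing, basket-less and all NPCs, 261 in each control and 1127 in input, and ADE17 at 354, 1469 and 1245 CPM against 151 in the GFP control and 768 in input. Over the matched controls the median of the 10 was 0.08, 0.96 and 0.81. The fixed list of biosynthetic genes was lower in 20 of 29 and higher in 7 (median -0.71, ADE13 -2.30, URA5 -2.06), camera adjusted p = 0.0151 by Benjamini-Hochberg and adjusted p = 0.275 with an estimated correlation.

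Marker genes did not move together. URA3 fell over the matched controls in basket-containing pores (-2.62 ± 0.04), basket-less pores (-1.28) and all NPCs (-1.37), and so did TRP1 (-1.76, -1.52 and -1.49), while ADE2 rose (1.11, 1.57 and 1.45). URA3 was also far higher in both controls than in input, as given above. LEU2 was higher in basket-containing pores (1.22) and HIS3 lower (-0.65). For LEU2 in basket-less pores (0.16) and all NPCs (0.15) the sign turns with upper-quartile factors. Phosphate-responsive genes, the list nearest PHO89, were higher in 4 of 16 and lower in 12 in basket-containing pores (median -0.61), not called. In the other pore groups the list went the other way. Its median against input was 0.90 in basket-less pores and 0.80 in all NPCs, above 0.66 in the GFP control.

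Lists given only as counts and medians are quoted for basket-containing over the PrA control and then basket-less over the GFP control. snoRNAs had 0 higher and 60 lower of 65 (median -2.61), then 1 and 55 (-1.52). Spliceosomal and other structured RNAs had 1 and 5 of 7 (-1.12), then 1 and 6 (-1.66), ribosomal RNA 0 and 3 of 5 (-6.05), then 0 and 4 (-3.93), and tRNA 0 and 3 of 5 (-1.16), then 0 and 3 with a median also below 0. Ty elements had 13 and 11 of 30 (-0.13), then 9 and 8 (0.09, a sign that turns with the scaling), and genes of the mitochondrial genome 1 and 2 of 4 (-0.72), then 2 and 2 (0.90). Alpha-cell markers had 1 and 1 of 4 (-0.09), then 1 and 2 (-0.54). The libraries were poly(A)-selected, and small nuclear and nucleolar RNAs made up only 0.011% of counts in basket-containing pores and 0.064% in the PrA control. Values of the noncoding and mitochondrial lists therefore describe what passed that selection, not how much of these RNAs came down. The same limit holds for RDN5-1 and COX1.

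With 3 libraries against 3, the number of genes called in the real split was 1 of 10 splits with as many in every other comparison, and 10 splits are too few for a share under 0.05. Over input the real values were 5749 for basket-containing pores (1 of 10), 5149 for basket-less pores (1 of 10) and 5252 for all NPCs (1 of 10), the highest other being 0. Over matched controls they were 5804, 5307 and 5431 (1 of 10 each), the highest other 0. Between kinds of pore they were 5303 for basket-containing over basket-less, 5167 for basket-containing over all NPCs and 2773 for basket-less over all NPCs, the highest other 0. For the difference with controls taken off it was 4895 with 33 as the highest other.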
